A study of Mus musculus with 8 samples.

How the data were processed

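Transcript levels were measured on 8 mouse expression arrays from Affymetrix, each with 45101 probe sets, with 2 arrays in each of 4 groups. The Tfh group held CXCR5-positive CD4 T cells sorted by flow cytometry from spleens of C57BL/6 mice 7 days after immunization with keyhole limpet haemocyanin, and then stimulated for 4 h with an antibody to CD3. The Th1, Th2 and Th17 groups were naive CD4 T cells from OT-II mice, whose T cell receptor recognizes an ovalbumin peptide. These cells were cultured for 5 days with peptide and antigen-presenting cells under the cytokine conditions that drive each type. RNA was extracted with Trizol and labelled with biotin by in vitro transcription.

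Per the labels the authors summarized the arrays with GCRMA, which corrects background from probe sequence, quantile-normalizes and summarizes each probe set. The version, and which arrays were normalized together, were not given in the sources used here. The deposited values are on the log2 scale, and they were analysed as deposited, with no further normalization in the fit behind the reported values. The number of arrays limits the precision.

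Probe sets were assigned to genes through the mouse gene tables supplied for GRCm38.p6, which served for names only, so genomic positions were not used here. Of the probe sets, 34945 were paired with 1 gene symbol, 932 with several, 9160 with none in these tables, and 64 were Affymetrix controls. For each of 18193 genes the probe set with the highest mean over the 8 arrays was kept. Genes above the 50th percentile of all values (3.13 on the log2 scale) in at least 2 arrays were tested, which left 11178.

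Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 8 arrays and empirical Bayes moderation with a trend on mean level (4 residual and 1.78 prior degrees of freedom). All tests were two-sided. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over the tested genes and its absolute log2 fold change was at least 1. The comparisons were Tfh against each cultured type, against their mean, and in the same direction against all 3, each pair of cultured types, and genes higher in 1 cultured type than in both others. The standard error (SE) is that of the moderated fit, and the SD is over the 2 arrays of a group.

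The 19 gene lists were markers of Tfh, Th1, Th2, Th17 and regulatory T cells, TGF-beta responsive genes, the early response to T cell receptor signalling, naive and memory T cell genes, cell cycle, glycolysis, cholesterol synthesis, interferon response, secreted cytokines, chemokine receptors, heat shock and integrated stress, and markers of B cells, of myeloid and dendritic cells, of CD8 and NK cells, and of erythroid cells and platelets. Of their 414 entries 377 were on the array with a probe set of 1 symbol; the others were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, beside camera with an estimated correlation and the rotation test fry. Fry asks whether a list moves on balance in 1 direction against 0, and does not compare it with other genes.

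Genes named in the text were the called genes with the largest changes each way whose arrays did not overlap between the groups, 8 each way for Tfh against all 3 cultured types and for the cultured pairs and 4 each way for Tfh against a single type. Symbols ending in Rik and those starting with Gm or LOC and a digit were left out. To these were added the lineage genes Cxcr5, Bcl6, Il21, Pdcd1, Icos, Tbx21, Ifng, Gata3, Il4, Il5, Il13, Il17a and Foxp3, and the members of each list with the smallest adjusted p or, for lists of other cell types, the highest level in Tfh. These rules, the lists, the comparisons and all alternatives but 1 were fixed before the data were examined.

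Alternatives were quantile normalization over the 8 arrays, arrays shifted to the same median, other filters, other ways to choose or average probe sets, other variance models and fold thresholds, leaving out each array, the replicate number as a block, and fits on fewer arrays. Counting the averaged Tfh arrays as 1 replicate was added after the data were seen. A call "in all 3 scalings" held as deposited, after the median shift and after quantile normalization. The calling procedure was tested on simulated data with changes of known size. In comparisons of 2 groups it recovered 13.6% to 18.3% of changes of 1 log2 unit and 66.5% to 71.9% of changes of 2. A gene that was not called may therefore still differ. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.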

Results

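Expression was measured in T follicular helper (Tfh) cells taken from immunized mice and in Th1, Th2 and Th17 cells made in culture, with 2 arrays per group and 8 in all. The comparisons ask how Tfh cells, which help B cells, differ from the other helper types, and how those types differ from each other. The Tfh cells came from the spleen and were restimulated for 4 h, whereas the other types were cultured for 5 days, so cell type, source and handling changed together between Tfh and the rest. The labels do not say whether replicates came from separate animals or cultures, so a p measures the spread between samples, which may be technical.

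Deposited values were distributed differently in the Tfh arrays. Their 65th percentiles were 6.91 and 6.98 on the log2 scale, against 5.23 to 5.31 in the 6 cultured arrays. The Tfh arrays also resembled each other more closely, with 11 tested genes differing by more than 1 log2 unit, against 1435 between the Th1 arrays, 696 between the Th2 arrays and 1339 between the Th17 arrays. The correlation across probe sets, which are not independent replicates, was 0.998 for the Tfh pair and 0.982 to 0.989 for the cultured pairs. Th1 replicate 1 correlated more with Th17 replicate 1 (0.98396) than with Th1 replicate 2 (0.9818), and Th1 replicate 2 more with Th17 replicate 2 (0.98222). Over the tested genes alone, Th1 replicate 1 was again nearer Th17 replicate 1 (0.9656) than Th1 replicate 2 (0.9637). Th1 replicate 2 was then nearer Th1 replicate 1 than Th17 replicate 2 (0.9616), and the Th17 arrays were nearest each other (0.9659). The correlation thus grouped the Th1 and Th17 arrays by type only in part. The median gene lay 0.85, 0.84 and 0.83 log2 units higher in Tfh than in Th1, Th2 and Th17, and quantile normalization turned this shift to -0.16 in each. Changes of single genes in Tfh are given as deposited and so hold this shift, with the value relative to the median gene beside the leading genes. Counts of calls that held in all 3 scalings are given beside the others. Both other scalings lower Tfh on balance, so a gene called lower in Tfh as deposited could hardly fail them. Against the mean of the cultured types 741 of 745 lower calls held, against 1420 of 4887 higher calls. For lower calls in Tfh this check is therefore weak. Counts of list members that rose or fell are to be read against these shares of the 11178 tested genes.

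**Figure D1:**
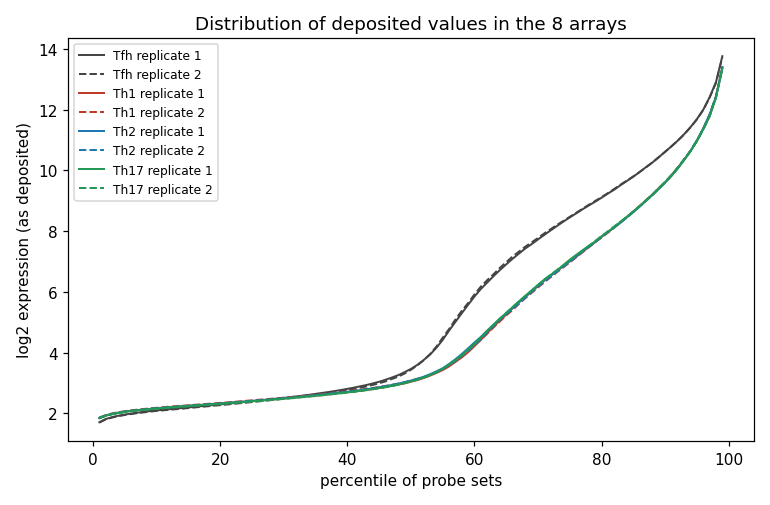
Log2 expression as deposited (vertical axis) at each percentile of the probe sets (horizontal axis) in the 8 arrays; solid and dashed lines are replicates 1 and 2. The Tfh arrays reach 6.91 and 6.98 at the 65th percentile and the cultured arrays 5.23 to 5.31.

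The sorted Tfh group was high in the receptor and the transcription factor by which Tfh cells are known. Cxcr5, the chemokine receptor that leads T cells into B cell follicles and by which these cells were sorted, stood at 11.23 ± 0.04 (SD, n = 2) in Tfh, against 4.35 ± 1.43 in Th1, 6.02 ± 0.94 in Th2 and 7.07 ± 1.48 in Th17. Bcl6, the repressor that directs Tfh differentiation, was 4.71, 3.78 and 4.41 log2 units higher in Tfh than in Th1, Th2 and Th17 (SE 0.87), or 3.86, 2.94 and 3.58 relative to the median gene. The inhibitory receptor gene Pdcd1 was higher by 2.63, 2.90 and 3.22 (SE 0.43), or 1.78, 2.06 and 2.40 relative to the median gene. The differences in Cxcr5 relative to the median gene were 6.03, 4.37 and 3.33. Foxp3, the regulator that defines regulatory T cells, stood at 10.76 in Tfh and 2.38 on average in the cultured types, a difference of 8.38 (SE 0.08, adjusted p = 2.02e-07) or 7.54 relative to the median gene. It belongs to the regulatory T cell list and not to the Tfh markers, and which of the sorted cells expressed it was not tested. All of these calls held in all 3 scalings and both Tfh arrays lay above all 6 others. The call for Cxcr5 against Th17 ended without Tfh replicate 1 (adjusted p = 0.0561) or 2 (0.0535), and that for Bcl6 against Th2 without Tfh replicate 1 (0.0537), Tfh replicate 2 (0.0513) or Th2 replicate 2 (0.0554).

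**Figure D2:**
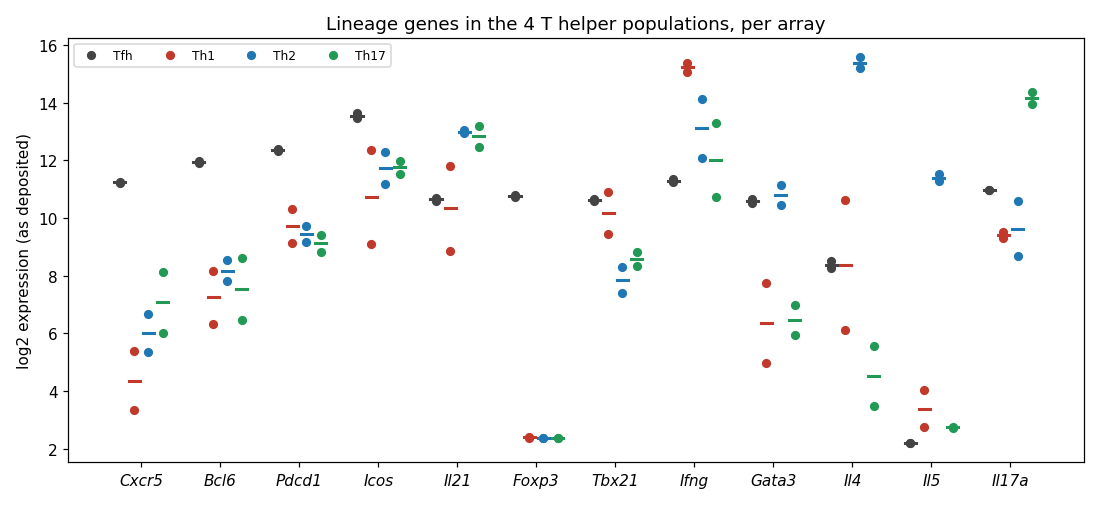
Log2 expression as deposited (vertical axis) of 12 lineage genes (horizontal axis) in the 4 groups; points are arrays and bars are means of 2 arrays. Cxcr5 was 11.23 in Tfh, Il4 15.39 in Th2 and Il17a 14.14 in Th17.

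Not every gene of the Tfh programme was called higher in Tfh. Il21, the cytokine by which Tfh cells help B cells, stood at 10.64 ± 0.07 in Tfh, 10.33 ± 2.08 in Th1, 13.00 ± 0.06 in Th2 and 12.83 ± 0.52 in Th17, and was called in none of the 3 comparisons. Against Th1 its direction hung on single arrays: it was called higher in Tfh without Th1 replicate 1 (1.78, adjusted p = 0.00768) and lower without Th1 replicate 2 (-1.15, adjusted p = 0.0288). The costimulator Icos stood at 13.54 in Tfh and 10.71 to 11.75 in the cultured types. It was higher in Tfh by 2.83, 1.81 and 1.79 against Th1, Th2 and Th17, but these differences missed the threshold (adjusted p = 0.0515, 0.168 and 0.172). Its 2 other probe sets gave 3.34 to 3.35, 2.36 to 2.69 and 2.28 to 2.30. For Il21 another probe set gave 2.23, -0.92 and -1.48, where the one above gave 0.31, -2.35 and -2.19. Of 21 tested Tfh markers 14 were higher in Tfh than in the mean of the cultured types, 0 were lower in limma (also 0 at an unadjusted p under 0.05) and 7 were neither; the count was also 14 when adjusted over the list alone, and 10 held in all 3 scalings. Among them Tox, a nuclear factor of the Tfh programme, was higher by 7.88 (SE 0.61), Sostdc1 by 6.44 (SE 0.06) and Cebpa by 5.14 (SE 0.06). The list as a whole did not pass camera (adjusted p = 0.164, and 0.795 with an estimated correlation), although it did after quantile normalization (adjusted p = 0.0014).

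The genes with the largest rise in Tfh against every cultured type included products of granulocytes. Ngp and Camp, which encode granule proteins, stood at 13.08 ± 0.08 and 11.42 ± 0.09 in Tfh and at 2.56 and 2.22 on average in the cultured types, 9.68 higher for Ngp relative to the median gene. Lcn2 and Ltf, the genes for the iron-binding proteins lipocalin 2 and lactoferrin, were higher by 9.32 (SE 0.28) and 8.93 (SE 0.11), and S100a9, a calcium-binding protein of myeloid cells, by 9.96 (SE 2.01). S100a9 also stood at 10.5 in Th2 replicate 1 and 5.50 in Th17 replicate 1, against 2.61 to 2.63 in the other 4 cultured arrays. The call for S100a9 against Th17 ended without Tfh replicate 1 (adjusted p = 0.0603), Tfh replicate 2 (0.0595) or Th17 replicate 2 (0.0634). St6galnac3, a sialyltransferase gene, and Pou6f1, a homeobox gene, were higher by 7.98 (SE 0.09) and 7.93 (SE 0.08). Genes that fell in Tfh against every cultured type were ranked by the smallest of their 3 falls. The leading 8 are given with their change against the mean of those types. They included Crabp2, which encodes a retinoic acid carrier (-8.70, SE 0.36, or -9.54 relative to the median gene), Cth, an enzyme of cysteine synthesis (-7.21, SE 1.10), Gja1, the gap junction protein connexin 43 (-6.82, SE 0.18), and Hacd1 (-6.37, SE 0.24). The others were Ermn (-6.37, SE 1.31), Tspan4 (-5.52, SE 0.33), the adenylate kinase gene Ak4 (-5.35, SE 0.61) and Nkain1 (-5.31, SE 0.66). Against all 3 cultured types 4390 of 11178 genes changed in the same direction, 3953 higher and 437 lower. After the median shift the counts were 1144 and 2421, after quantile normalization 1240 and 1709, and 988 and 434 held in all 3 scalings. Independent lists would share 854 genes higher and 2.93 lower, and simulated unchanged groups with a common Tfh reference shared 0 in the same direction in 100 draws. That simulation held no effects and no shift of the Tfh arrays, so it cannot measure what these add to the overlap. Part of the excess may come from the shift, with 3953 higher genes as deposited and 1144 after the median shift. Part may come from the Tfh arrays that the 3 comparisons share.

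Most members of the interferon response list were called higher in Tfh than in the mean of the cultured types, while the list as a whole did not pass its test in this comparison as deposited. Oasl2 and Rsad2, which encode antiviral proteins, stood at 10.19 and 10.53 in Tfh and were higher by 7.42 (SE 0.35) and 7.04 (SE 0.39), and Irf7, a regulator of interferon genes, by 6.04 (SE 0.40). Of 22 tested members 15 rose, 0 fell in limma (also 0 at an unadjusted p under 0.05) and 7 were neither, also 15 adjusted over the list alone, and 12 held in all 3 scalings. The camera test gave an adjusted p = 0.0957 as deposited and 0.869 with an estimated correlation, and the list passed after quantile normalization (0.000342). Its median over arrays was 11.1 and 11.5 in the Tfh arrays, 10.5 in Th17 replicate 2 and 7.09 to 8.52 in the others. Against Th2 alone the list passed camera as deposited, upward (adjusted p = 0.0442), but not with an estimated correlation (0.748). The call against Th2 ended without either Tfh replicate, either Th1 replicate or Th2 replicate 1.

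Single genes of resting T cells and of TGF-beta signalling were called, though neither list passed camera as deposited. Klf2, which keeps T cells quiescent and recirculating, rose by 6.08 (SE 0.35), and Il6ra, a subunit of the interleukin 6 receptor, by 5.26 (SE 0.32). Of 18 naive and memory T cell genes 13 rose, 1 fell and 4 were neither, the same counts adjusted over the list alone, with 6 higher and 1 lower in all 3 scalings (camera adjusted p = 0.5, and 0.869 with an estimated correlation); the list passed, upward, after quantile normalization (adjusted p = 0.024). Of 15 TGF-beta responsive genes 10 rose, 2 fell and 3 were neither, with 10 and 2 adjusted over the list alone and 6 and 2 in all 3 scalings (camera adjusted p = 0.783). Ldlrad4 and Smad7, both inhibitors of the pathway, rose by 5.77 (SE 0.11) and 2.47 (SE 0.22). Of 11 regulatory T cell genes 6 rose, 1 fell and 4 were neither, with 6 and 1 adjusted over the list alone and 2 and 1 in all 3 scalings (camera adjusted p = 0.782); Ikzf2, the gene for the regulatory T cell factor Helios, rose by 6.90 (SE 0.70).

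Of 32 genes of the early response to T cell receptor signalling 14 rose, 4 fell and 14 were neither, with 14 and 4 adjusted over the list alone and 3 and 4 in all 3 scalings. Among all 11178 tested genes 4887 were called higher, and 1420 in all 3 scalings, so the number that rose does not set the list apart. Fosb, a component of the AP-1 factor, rose by 4.24 (SE 0.12), and Zfp36, which encodes a protein that speeds decay of cytokine messages, by 3.63 (SE 0.21). The median of the list lay 0.42 above the median gene, while the mean (-0.15) and camera (adjusted p = 0.507) pointed down as deposited and camera pointed up after quantile normalization (adjusted p = 0.287).

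Single genes of the cell cycle, glycolysis, stress and cholesterol synthesis lists were called lower in Tfh, and no list-level call among them held with an estimated correlation. Of 34 cell cycle genes 0 rose in limma (2 at an unadjusted p under 0.05), 6 fell and 28 were neither, also 6 lower adjusted over the list alone and in all 3 scalings; Cdc6, which licenses replication origins, fell by 3.03 (SE 0.27) and Rrm2, which encodes a subunit of ribonucleotide reductase, by 1.34 (SE 0.19). The list passed camera as deposited (adjusted p = 2.76e-05) and after quantile normalization (0.000342), but not with an estimated correlation (adjusted p = 0.795). Of 20 glycolysis genes 4 rose, 6 fell and 10 were neither, with 4 and 6 adjusted over the list alone and 0 and 6 in all 3 scalings; the enzyme gene Pgk1 fell by 1.55 (SE 0.12). The camera call (adjusted p = 0.000614) was lost with an estimated correlation (adjusted p = 0.795) and after quantile normalization (0.167). Of 21 heat shock and integrated stress genes 2 rose, 3 fell and 16 were neither, with 0 and 2 adjusted over the list alone and 0 and 3 in all 3 scalings (camera adjusted p = 0.000366, lost with an estimated correlation, adjusted p = 0.795, and after quantile normalization, 0.128); asparagine synthetase (Asns) fell by 3.37 (SE 0.67). Of 18 cholesterol synthesis genes 2 rose, 1 fell and 15 were neither, with 0 and 1 adjusted over the list alone and in all 3 scalings (camera adjusted p = 0.103); Hsd17b7, a late enzyme of the pathway, fell by 1.88, a call that ended without Tfh replicate 1 (adjusted p = 0.0645) or 2 (0.0581).

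**Figure D3:**
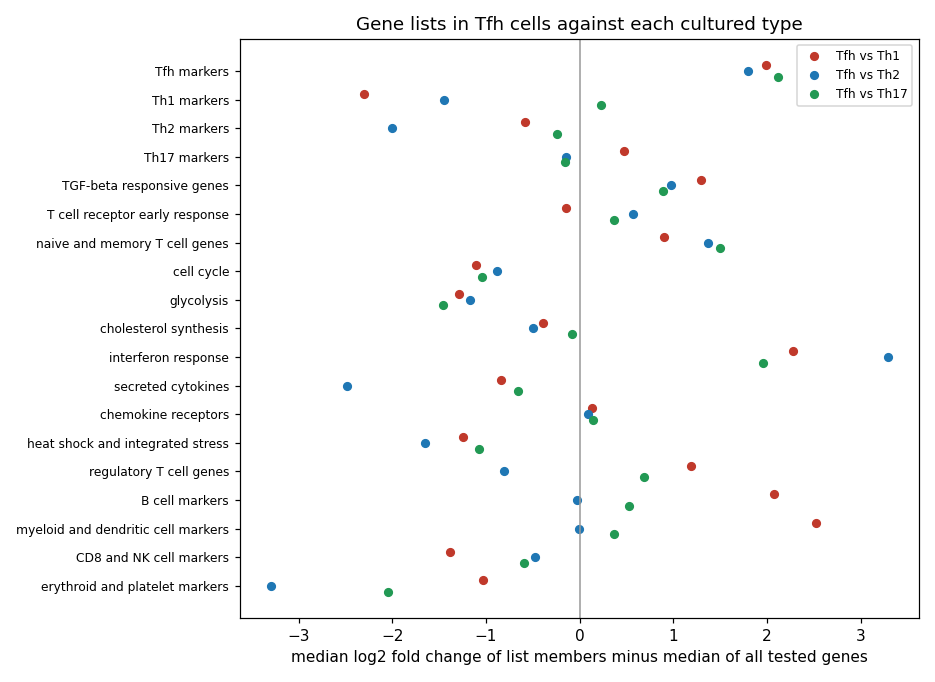
Median log2 fold change of the members of each gene list minus the median of all tested genes (horizontal axis) for the 19 lists (vertical axis); each point is 1 comparison of Tfh with a cultured type. The interferon response list lay 2.27, 3.29 and 1.96 above the median gene against Th1, Th2 and Th17.

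Secreted cytokine genes were called both ways. Csf2, the growth factor GM-CSF, stood at 8.70 in Tfh and fell by 3.49 (SE 0.32) against the mean of the cultured types. Of 24 members 4 rose, 6 fell and 14 were neither, with 3 and 6 adjusted over the list alone and 2 and 6 in all 3 scalings. The camera call (adjusted p = 0.000366) was lost with an estimated correlation (adjusted p = 0.196) and after quantile normalization (0.207). Of 14 chemokine receptor genes 6 rose, 1 fell and 7 were neither, with 6 and 1 adjusted over the list alone and 4 and 1 in all 3 scalings. With 4887 of all 11178 tested genes called higher, the number that rose does not set the list apart. Ccr6, a receptor of Th17 and B cells, rose by 6.24 (SE 0.44). The median of the chemokine receptor genes lay 0.09 below the median gene and their mean 0.62 above it, with camera down as deposited (adjusted p = 0.782) and up after quantile normalization (0.355).

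Among markers of other cell types, the myeloid, B cell and CD8 and NK lists did not pass camera. Of 20 myeloid and dendritic cell markers 7 rose in Tfh, 2 fell and 11 were neither, with 6 and 2 adjusted over the list alone and 4 and 2 in all 3 scalings; the median lay 0.66 and the mean 1.41 above the median gene, while camera pointed down as deposited (adjusted p = 0.507) and up after quantile normalization (0.331). Their median level was 8.25 and 8.17 in the Tfh arrays but also 9.14 in Th2 replicate 1, against 2.71 in Th1 replicate 1. Of 19 B cell markers 9 rose, 0 fell and 10 were neither, with 9 adjusted over the list alone and 3 in all 3 scalings (camera adjusted p = 0.918). The number that rose lay near the share of all genes, 4887 of 11178. The invariant chain gene Cd74 stood at 12.03 in Tfh and 10.33 on average in the cultured types. Of 11 CD8 and NK cell markers 3 rose, 2 fell and 6 were neither, the same adjusted over the list alone and 2 and 2 in all 3 scalings (camera adjusted p = 0.5). The granzyme genes Gzmk and Gzma moved apart, by 5.54 (SE 0.50) and -4.47 (SE 1.11). Of 5 erythroid and platelet markers 0 rose, 1 fell and 4 were neither, the same adjusted over the list alone and in all 3 scalings. The camera call (adjusted p = 0.0256) was lost with an estimated correlation (adjusted p = 0.629), after quantile normalization (0.207) and without Tfh replicate 2 (0.0663). Their median was 9.90 in Th2 replicate 1 and 6.36 in Th17 replicate 1, against 3.31 to 4.08 in the other arrays.

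Against the mean of the cultured types 5632 genes were called, 4887 higher and 745 lower. After the median shift the counts were 1653 and 3233, after quantile normalization 1756 and 2463, and 1420 and 741 held in all 3 scalings.

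Compared with Th1 cells, Tfh cells were lower in several Th1 effector genes. Ifng, the cytokine that defines Th1 cells, stood at 11.29 ± 0.07 in Tfh and 15.23 ± 0.23 in Th1 (-3.93, SE 0.97, adjusted p = 0.0141, or -4.78 relative to the median gene). Nkg7, a gene of cytotoxic granules, fell by 7.93 (SE 0.89), Gzmc, a granzyme gene, by 8.37 (adjusted p = 0.0041), Il3, a haematopoietic cytokine gene, by 9.02 (SE 1.04), and Il12rb2, the signalling subunit of the interleukin 12 receptor, by 6.21 (SE 0.88). Tbx21, the Th1 master regulator, was not called (0.46, SE 0.54). Of 17 Th1 markers 2 rose, 6 fell and 9 were neither, also 2 and 6 adjusted over the list alone, with 0 and 6 in all 3 scalings. The camera call (adjusted p = 0.000318) was lost with an estimated correlation (adjusted p = 0.217) and after quantile normalization (0.105). Of the 19 B cell markers 12 rose and of the 20 myeloid markers 9 rose, with 5 of each in all 3 scalings (camera adjusted p = 0.268 and 0.693). After quantile normalization both lists passed camera, upward (adjusted p = 0.0102 and 0.0417). Gata3, the Th2 regulator, was higher in Tfh than in Th1 by 4.25 (SE 0.91), and Ccr6 by 7.80 (SE 0.54). In all 5469 genes were called, 4780 higher and 689 lower. The split was 1605 and 3190 after the median shift and 1747 and 2365 after quantile normalization, and 1381 and 683 held in all 3 scalings. The Ifng call ended without Tfh replicate 1 (adjusted p = 0.0627), Tfh replicate 2 (0.0664) or Th1 replicate 1 (0.0592).

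Compared with Th2 cells, Tfh cells were lower in the Th2 cytokine genes Il5, Il4 and Il13. Il5, which drives eosinophils, stood at 2.20 ± 0.01 in Tfh and 11.39 ± 0.16 in Th2 (-9.19, SE 0.40, adjusted p = 2.19e-05, or -10.03 relative to the median gene). Il4, the B cell and Th2 cytokine gene, was 8.37 ± 0.17 in Tfh and 15.39 ± 0.26 in Th2 (-7.02, SE 1.47), and Il13 lay at 6.78 and 11.31 (-4.53, SE 1.32). The cytokine gene Il24, the steroid enzyme gene Akr1c18 and the neurotensin gene Nts fell by 12.38 (SE 2.40), 11.39 (SE 0.90) and 9.96 (SE 1.57). Gata3 differed by -0.19 (SE 0.91) and was not called. The Il13 call ended without Tfh replicate 1 (adjusted p = 0.082), Tfh replicate 2 (0.107), Th2 replicate 1 (0.0911) or Th2 replicate 2 (0.0818). Of 17 Th2 markers 0 rose, 8 fell and 9 were neither, also 8 lower adjusted over the list alone and in all 3 scalings. Their camera call (adjusted p = 6.21e-05) held after quantile normalization (0.0256) and was lost with an estimated correlation (adjusted p = 0.298). Of the 19 B cell markers 3 rose and of the 20 myeloid markers 4 rose and 2 fell, with 1 higher, and 1 higher and 2 lower, in all 3 scalings (camera adjusted p = 0.382 and 0.0705). Of 5 erythroid and platelet markers 2 fell, also in all 3 scalings, and 1 adjusted over the list alone, with a median 3.30 below the median gene. Their camera test passed as deposited (adjusted p = 0.0103) but not with an estimated correlation (adjusted p = 0.523) or after quantile normalization (0.138). In all 5554 genes were called, 4784 higher and 770 lower. The split was 1680 and 3248 after the median shift and 1803 and 2381 after quantile normalization, and 1452 and 767 held in all 3 scalings.

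Compared with Th17 cells, Tfh cells were lower in Il17a, the signature cytokine of Th17 cells, with 10.98 ± 0.00 in Tfh and 14.14 ± 0.29 in Th17 (-3.16, SE 0.59, adjusted p = 0.00476, or -3.99 relative to the median gene), and higher in Ccr6, the chemokine receptor of Th17 cells (2.82, SE 0.54). Gata3 was higher in Tfh by 4.14 (SE 0.91), a call that ended without Tfh replicate 1 (adjusted p = 0.0509). Of 16 Th17 markers 4 rose, 2 fell and 10 were neither, the same adjusted over the list alone, with 1 and 2 in all 3 scalings (camera adjusted p = 0.17). B cell markers rose in 5 of 19 cases and myeloid markers in 4 of 20, with 1 myeloid marker lower; 2 B cell markers, and 3 myeloid markers higher and 1 lower, held in all 3 scalings (camera adjusted p = 0.683 and 0.462). Of 5 erythroid and platelet markers 1 fell, also in all 3 scalings (camera adjusted p = 0.0426, lost with an estimated correlation, adjusted p = 0.715, and after quantile normalization, 0.267). That call also ended without Tfh replicate 2 (0.0887), Th1 replicate 1 or 2 (0.0593), or Th17 replicate 1 (0.0541) or 2 (0.0568). The macrophage elastase gene Mmp12 and Serpinf1, which encodes a secreted anti-angiogenic factor, fell by 7.98 (SE 1.34) and 7.90 (SE 1.27). Among the largest changes were the X inactivation transcript Xist (11.28, SE 3.10) and the Y-linked gene Eif2s3y (-8.00, SE 2.58). The Xist call ended without Tfh replicate 1 (adjusted p = 0.0825) or 2 (0.0869) or Th17 replicate 1 (0.0719) or 2 (0.0748). That for Eif2s3y ended without Tfh replicate 1 (0.122) or 2 (0.123), Th1 replicate 1 (0.0579) or 2 (0.0578), or Th17 replicate 1 (0.102) or 2 (0.116). In all 5357 genes were called, 4667 higher and 690 lower. The split was 1514 and 2903 after the median shift and 1561 and 2266 after quantile normalization, and 1299 and 685 held in all 3 scalings.

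Among the cultured types, single genes of the Th1 and Th2 marker lists were called between Th1 and Th2 cells. Stat4, which carries the interleukin 12 signal, stood at 11.73 ± 0.31 in Th1 and 9.11 ± 0.05 in Th2, higher in Th1 by 2.62 (SE 0.17, adjusted p = 0.00336), and the membrane protein gene Ms4a4b was higher by 5.11 (SE 0.34). In Th2, Il5 was higher with 11.39 against 3.39 in Th1 (-8.00, SE 0.40), and so was Epas1, a hypoxia-inducible factor gene, with 12.24 against 3.64 (-8.60, SE 0.56). Akr1c18 (-10.16, SE 0.90) and the chemokine genes Ccl24 (-7.61, SE 0.66) and Ccl17 (-6.59, SE 0.62) were also called lower in Th1. Several lineage genes differed widely without passing: Il4 by -7.03 (adjusted p = 0.103), Gata3 by -4.44 (0.0997), Tbx21 by 2.32 (0.127) and Ifng by 2.12 (0.374). Of 17 Th2 markers 1 was higher in Th1, 5 were lower and 11 were neither, and 1 and 9 adjusted over the list alone. Their camera call (adjusted p = 9.67e-10) was lost with an estimated correlation (adjusted p = 0.184). Of 17 Th1 markers 1 was higher, 0 were lower and 16 were neither in limma, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000731, and 0.29 with an estimated correlation).

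B cell and myeloid markers varied between arrays of the same type. Their medians were 3.42 and 5.33 for B cell markers in Th1, 5.08 and 7.59 in Th2 and 7.18 and 5.40 in Th17, and 2.71 and 4.81, 9.14 and 5.62, and 7.44 and 5.06 for myeloid markers. None of the 19 B cell markers was called by limma between Th1 and Th2, but 5 were lower in Th1 adjusted over the list alone and 8 at an unadjusted p under 0.05, with a median 1.70 below the median gene (camera adjusted p = 7.49e-07, and 0.384 with an estimated correlation). Of 20 myeloid markers 1 was lower, with 4 adjusted over the list alone (camera adjusted p = 2.28e-07, and 0.384 with an estimated correlation). Erythroid and platelet markers lay a median 3.05 below the median gene in Th1 (camera adjusted p = 0.0432, lost with an estimated correlation, adjusted p = 0.384, and after quantile normalization, 0.055), with 0 of 5 members called by limma and 1 lower at an unadjusted p under 0.05. Their call ended without Th2 replicate 1 (0.609), Th1 replicate 1 (0.118) or Th1 replicate 2 (0.155).

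In all 139 genes were called between Th1 and Th2, 39 higher in Th1 and 100 lower, with 1754 at an unadjusted p under 0.05. The pooled spread took in the closely matched Tfh arrays: without Tfh replicate 1 the count was 27, without Tfh replicate 2 it was 26, and in a fit on the 6 cultured arrays it was 28, all 28 among the 139. It was 0 with only the arrays of the 2 types in limma (1252 at an unadjusted p under 0.05), 238 without Th1 replicate 2 and 212 without either Th17 replicate. In simulated data with the Tfh spread as measured, a mean of 10.15 and at most 18 unchanged genes were called here. Il5, Epas1, Stat4, Ms4a4b and Il9 were called whichever array was left out and on the 6 cultured arrays; Akr1c18, Ccl24 and Ccl17 were not called without Tfh replicate 1 (adjusted p = 0.0594, 0.0571 and 0.0677) or 2 (0.0595, 0.058 and 0.0677).

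Th1 and Th17 cells differed least in number of calls. Serpinb9, an inhibitor of granzyme B, stood at 12.21 ± 0.16 in Th1 and 8.62 ± 0.17 in Th17, higher in Th1 by 3.59 (SE 0.15, adjusted p = 0.00231), and the related gene Serpinb6b was higher by 4.40 (SE 0.32). Il1r1, the interleukin 1 receptor gene, was lower in Th1 with 4.08 ± 0.02 against 8.28 ± 0.37 (-4.20, SE 0.26). Il17a differed by -4.73 (adjusted p = 0.0698), Ccr6 by -4.98 (0.0513) and Ifng by 3.21 (0.359), and none of these passed. Of 17 Th1 markers 0 were called by limma over all genes and 7 were higher adjusted over the list alone, with 8 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 1.68e-05, and 0.107 with an estimated correlation). Of 16 Th17 markers 1 was lower, and 4 adjusted over the list alone (camera adjusted p = 3.03e-05, and 0.107 with an estimated correlation). None of the markers of other cell types was called by limma over all genes, and their camera calls were lost with an estimated correlation. B cell markers pointed down in Th1 (6 of 19 lower adjusted over the list alone, 9 at an unadjusted p under 0.05; camera adjusted p = 1.78e-05, and 0.478 with an estimated correlation). Myeloid markers pointed down (0 and 3 of 20; camera adjusted p = 0.000628, and 0.714 with an estimated correlation) and CD8 and NK markers up (1 of 11 by either count; camera adjusted p = 0.00895, and 0.44 with an estimated correlation). Without Th17 replicate 1 the B cell (adjusted p = 0.0515), myeloid (0.204) and CD8 and NK (0.0515) calls ended, and without Th1 replicate 1 the myeloid (0.0825) and CD8 and NK (0.379) calls.

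The count was 16 genes, 7 higher in Th1 and 9 lower, with 1087 at an unadjusted p under 0.05, while simulated data with the Tfh spread as measured gave a mean of 11.45 and at most 22 calls among unchanged genes. It was 3 without Tfh replicate 1, without Tfh replicate 2 or on the 6 cultured arrays (Serpinb9, Stard8 and Ahrr), 10 without either Th2 replicate, 112 and 71 without Th1 replicates 1 and 2, and 70 and 50 without Th17 replicates 1 and 2. With the replicate number as a block it was 5, without a filter 9, and with only the arrays of the 2 types 0 in limma (535 at an unadjusted p under 0.05). The call for Serpinb6b ended without either Tfh replicate (adjusted p = 0.128) and without Th2 replicate 1 (0.055) or 2 (0.0533), and that for Il1r1 without Tfh replicate 1 (0.113) or 2 (0.112).

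Single cytokine genes were called between Th2 and Th17 cells. Il5 was 11.39 ± 0.16 in Th2 and 2.74 ± 0.03 in Th17, higher in Th2 by 8.65 (SE 0.40, adjusted p = 0.000815), Epas1 by 9.07 (SE 0.56) and Il4 by 10.88 (SE 1.47, adjusted p = 0.0497). Tanc2, which encodes a scaffold protein, was higher by 6.21 (SE 0.14). Il17a was lower in Th2 with 9.63 ± 1.35 against 14.14 ± 0.29 (-4.51, SE 0.59), as were Ccr6 (-5.30, SE 0.54) and the transcriptional inhibitor gene Id3 (-3.75, SE 0.50). Of 24 secreted cytokine genes 3 were higher in Th2, 1 was lower and 20 were neither, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.00283, and 0.152 with an estimated correlation). Of 17 Th2 markers 3 were higher in Th2, 0 lower and 14 neither, and 10 were higher adjusted over the list alone. Their camera call (adjusted p = 2.44e-09) was lost with an estimated correlation (adjusted p = 0.152). Of 16 Th17 markers 1 was higher, 2 were lower and 13 were neither, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.18). The myeloid list had 0 of 20 members called by limma and 3 higher in Th2 adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.0194, and 0.87 with an estimated correlation), and its median was 9.14 in Th2 replicate 1. Without that array its camera call ended and pointed down (adjusted p = 0.951), and it ended without Th17 replicate 2 (0.423).

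In all 75 genes were called, 54 higher in Th2 and 21 lower, with 1510 at an unadjusted p under 0.05 and a mean of 10.95 and at most 19 false calls in the simulated data. The count was 22 without either Tfh replicate, 26 on the 6 cultured arrays, all 26 among the 75, and 5 with only the arrays of the 2 types; it was 121 and 128 without Th1 replicates 1 and 2, 133 without Th2 replicate 2 and 161 without Th17 replicate 1. Il5, Epas1, Il9 and Tanc2 were called whichever array was left out, whereas the call for Il4 ended without any 1 of the Tfh, Th2 or Th17 arrays (adjusted p from 0.0699 to 0.184) and on the 6 cultured arrays (0.190), and that for Id3 without any of the same arrays (0.0827 to 0.176). The Il17a call ended without any 1 of the Tfh, Th1 or Th17 arrays (0.0656 to 0.172) and on the 6 cultured arrays (0.174), and the Ccr6 call without any 1 of the Tfh or Th2 arrays (0.064 to 0.0994).

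Th2 arrays held most of the genes that set 1 cultured type apart. The cells had been cultured with antigen-presenting cells. Medians of the myeloid markers were 9.14 and 5.62 in the Th2 arrays, 2.71 and 4.81 in Th1 and 7.44 and 5.06 in Th17. Whether the genes below came from the T cells was not tested. In Th2, 46 genes were higher than in both Th1 and Th17, among them Epas1 (8.60 above the higher of the others), Il5 (8.00), Myo6, a motor protein gene (7.73), Ccl24 (6.91), Ccl17 (6.32) and Tanc2 (6.21). Th1 cells had 5 such genes, H2-Q5, Adgre5, Clcf1, Serpinb9 and Cracdl, and Th17 cells had 3, Ppp1r14c, Stard8 and Ahrr. Ahrr and Stard8 stood at 3.48 and 4.12 in Th17, near the lower end of the scale, where GCRMA values vary little between arrays. Of the Th2 genes above, limma on the 6 cultured arrays called Epas1 and Il5 against both other types. It did not call Myo6 against Th1 (adjusted p = 0.0832) or Th17 (0.104), nor Ccl24 (0.0637 and 0.0935) or Ccl17 (0.0728 and 0.0997).

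Independent lists would share 0.483 genes for Th2, 0.0244 for Th1 and 0.0169 for Th17, and simulated unchanged groups shared a mean of 0.02, 0 and 0. That simulation held no real differences, so it does not measure what shared arrays add. Part of the excess may come from the shared arrays of the type. The Th2 count was 18 and 17 without Tfh replicates 1 and 2, 102 without Th2 replicate 2 and 18 on the 6 cultured arrays. The Th1 count was 0 without either Tfh or either Th2 replicate and on the 6 cultured arrays, 38 and 26 without Th1 replicates 1 and 2, 11 without Th17 replicate 1, and 1 with the replicate number as a block or without a filter. The Th17 count was 2 without Tfh replicate 1, 9 and 8 without Th1 replicates 1 and 2, 5 without either Th2 replicate, and 36 and 24 without Th17 replicates 1 and 2.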

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

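Control probe sets, which no comparison uses, were to be looked at from the start, but comparing the gap between arrays was chosen after their values were seen. The controls were bacterial transcripts that can be added to RNA before labelling, and their values are means over the probe sets of each. The dap control stood out in Tfh replicate 1, Th1 replicate 2, Th2 replicate 2 and Th17 replicate 2, with at least 9.07 on the log2 scale against at most 2.65 in the other 4 arrays, a gap of 6.422. The phe control was high in Tfh replicate 2 and Th2 replicate 1 (gap 5.765), thr in Th1 replicate 1 and Th17 replicate 2 (gap 5.215), and trp in Th2 replicate 2 and Th17 replicate 1 (gap 5.689). The lys control was high in none of the 8 arrays, with at most 2.63.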

How the results depend on the processing

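Counting the averaged Tfh arrays as 1 replicate was chosen after the data were seen; the other alternatives here were not. Of the counts under alternatives 263 lay within 1.5 times the reported count and 96 did not. Of the values of named genes 11828 kept direction and side of the threshold, 595 no longer passed and 160 newly passed. Direction changed in 9 that passed in at least 1 of the 2 fits and in 115 that passed in neither. For lists the numbers were 1599, 178, 86, 23 and 109. Where a lone array stands for a group, it is assumed to vary like the other groups. Genes near the lower end of the scale are limited by background, and the cause of the changes below was not tested unless stated.

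With 1 array left out, the counts ran from 4520 to 5535 for Tfh against Th1, 4679 to 5656 against Th2, 4377 to 5453 against Th17, 4843 to 5666 against their mean and 3610 to 4302 against all 3. They ran from 26 to 238 for Th1 against Th2, 3 to 112 for Th1 against Th17 and 22 to 161 for Th2 against Th17, and from 0 to 38, 17 to 102 and 2 to 36 for genes higher in Th1, Th2 and Th17 alone. Lists called ran from 5 to 7, 6 to 8, 3 to 7 and 6 to 8 for Tfh against Th1, Th2, Th17 and their mean, 7 to 11 for Th1 against Th2, 4 to 10 for Th1 against Th17 and 3 to 9 for Th2 against Th17.

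With all probe sets, which tests more features, the counts were 13546, 13706, 13426, 13917 and 11401 for Tfh against Th1, Th2, Th17, their mean and all 3, 232 for Th1 against Th2, 127 for Th2 against Th17, and 10, 76 and 6 for genes higher in Th1, Th2 and Th17 alone. With an absolute log2 fold change of at least 2 they were 2531, 2644, 2310, 2471 and 1732 for the Tfh comparisons in that order, 10 for Th1 against Th17, and 2 and 1 for Th1 and Th17 alone. Without a filter Th1 against Th17 gave 9 and Th1 alone 1; with the replicate number as a block they gave 5 and 1. Th17 alone gave 6 after the median shift and 5 with the mean of probe sets.

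With the Tfh arrays averaged, Th1 against Th2, Th1 against Th17 and Th2 against Th17 gave 26, 3 and 22, and Th1 and Th2 alone 0 and 17. On the 6 cultured arrays they gave 28, 3 and 26 (1220, 723 and 1042 at an unadjusted p under 0.05), and Th1 and Th2 alone 0 and 18. With only the 2 groups compared limma gave 0, 0 and 5 (1252, 535 and 1142 unadjusted). Deviations of replicate 1 correlated between groups by -0.002 to 0.0424 for 4 pairs of groups, 0.255 for Th1 and Th17 and 0.268 for Th2 and Th17. The labels do not say that equal numbers belong together, so the numbers entered only the blocked fit.

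With an estimated correlation camera called 0 lists in each of the 7 comparisons. Fry called 12, 8 and 12 for Tfh against Th1, Th17 and the mean, 4 for Th1 against Th2 and 2 for Th1 against Th17. After quantile normalization camera called 5, 3 and 4 for Tfh against Th2, Th17 and the mean, not all of them lists called as deposited; without a filter the numbers were 1, 0 and 1, and 7 for Th2 against Th17. The rotation test fry of limma, which tests against 0 and so takes in the Tfh shift, turned several lists up: Th17 markers (adjusted p = 0.00772 against Th1, 0.0109 against the mean), early T cell receptor response (0.0235, 0.00529, 0.00673 and 0.00295 against Th1, Th2, Th17 and the mean), CD8 and NK markers (0.00772, 0.00352, 0.00673 and 0.00255), chemokine receptors (0.000272, 0.00495 and 0.000455 against Th2, Th17 and the mean), and Th1 markers and regulatory T cell genes against Th2 (0.308 and 0.000272).

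Single arrays turned lists between cultured types in camera, given with the range over the arrays left out. Without Th1 replicate 1 glycolysis (adjusted p = 0.0224; range 0.00165 to 0.881) and cholesterol synthesis (0.000374, the lowest, to 0.943) in Th1 against Th2 and cholesterol synthesis against Th17 (0.00166; range 2.1e-07 to 0.595) turned down. Without Th1 replicate 2 the cell cycle list turned down against Th2 (0.329, the highest, from 1.63e-09) and Th17 (0.175, the highest, from 2.85e-07), and glycolysis up against Th17 (0.0206; range 0.0004 to 0.496). Myeloid markers in Th2 against Th17 turned down without Th2 replicate 1 (0.951, the highest, from 4.57e-09), and heat shock genes in Th1 against Th17 without Th17 replicate 2 (0.00132; range 0.000237 to 0.651). Of named genes in Tfh, Cd8a turned to -0.11 after quantile normalization and -0.0779 after the median shift against the mean, and Slc4a1 after the median shift to -1.10, -1.08 and -1.10 against Th1, Th17 and the mean. With the probe set of largest variance Ccr9 against Th2 turned to -1.67 and Mvk to 1.77 and 1.79 against Th17 and the mean, and Il21 against Th1 ran from -1.15 without Th1 replicate 2 to 1.78 without Th1 replicate 1.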

Other observations

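The tests of granulocyte cells and of mice of different sex were written before their results were seen, and the other 4 tests here after. Among the genes higher in Th2 than in both other cultured types, some that fall outside the naming rule were chosen after their values were seen. Fabp4, which encodes a fatty acid carrier, stood at 6.86 in Th2, at most 3.41 in the other cultured types and 3.64 in Tfh, and Olr1, which encodes a receptor for oxidized lipoprotein, at 9.89, 7.07 and 4.22. Grhl1, a transcription factor gene, stood at 7.93 in Tfh against 4.75 in Th2.

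The 6 leading granulocyte genes were still higher in Tfh by a median of 9.255 after joint quantile normalization. As deposited they were higher by 8.93 to 10.5, while the 65th percentiles of the Tfh and cultured arrays lay about 1.60 apart. A gap of that size could not make up these differences, so the choice of genes fixed the outcome of the test in advance. Th2 replicate 1 and in part Th17 replicate 1 also stood apart in such genes, with S100a8 at 11.1 and 6.66, Mmp8 at 5.71 and 7.51 against 3.86 and 4.17 in the Tfh arrays, and Ctsg at 8.44 in Th2 replicate 1 against 5.92 and 6.07. Granulocytes or their RNA among the sorted cells may account for the Tfh values, although a gate on CD4 and CXCR5 should remove such cells: of 16 tested granulocyte genes not looked at before, 6 (37.5%) were called higher in all 3 scalings, against 12.7% of all tested genes. This lay between the bounds set in advance, with Mpo at 8.67 and 8.66 in the Tfh arrays but Cxcr2 at 4.03 and 4.01, under its 4.15 to 5.36 in the cultured arrays, so the explanation stays open. Expression of these genes by the T cells themselves was not tested.

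Sex-linked genes differed between arrays of the same group. Xist stood at 2.79 and 11.1 in the Th1 arrays, 5.48 and 11.9 in the Th2 arrays, 2.82 and 2.55 in the Th17 arrays and 13.8 and 14.1 in the Tfh arrays. Its difference of 6.446 between the Th2 arrays, which share a value distribution, argues against normalization as the cause of that difference. It is part of the pattern itself and does not bear on the Xist values of the Tfh arrays. Mice of different sex behind the arrays are a candidate explanation, since the other Y-linked genes tested, Kdm5d and Uty, were lower by at least 3.147 in both Tfh arrays and Th2 replicate 2 than in Th1 replicate 1. The labels do not give the sex, and Th1 replicate 2 was high in both Xist (11.1) and the Y-linked Eif2s3y (9.88).

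Most calls were higher in Tfh as deposited. Quantile normalization of all arrays together would have given them nearly the same distribution, whatever the cells expressed. The 65th percentiles were 6.91 and 6.98 in the Tfh arrays and 5.23 to 5.31 in the cultured arrays. This gap was 18.79 times the range of the cultured arrays. If GCRMA was run as the labels state, it argues against joint normalization, and so for Tfh arrays normalized apart from the others. Whether a real rise of most genes in Tfh cells adds to the gap stays open. The deposited values cannot tell, because arrays normalized apart need not share a scale. The hybridization controls, which are added at a fixed amount, shifted by a median of -0.04741 over 18 probe sets, from -2.01 to 0.505, against 0.839 for the median gene. Their SD of 0.838 was too wide a spread to decide by the bounds chosen for this test.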
